A study of Homo sapiens with 2 samples.

How the data were processed

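Total RNA of 2 cultures labelled SK-MEL-2, a human melanoma line, was measured by RNA sequencing. One culture had received DMSO, the solvent control, and the other JNJ-7706621 at 1.75 µM, both for 48 h. JNJ-7706621 is known as an inhibitor of cyclin-dependent kinases and Aurora kinases. Groups were taken from the sample labels, with 1 library per group.

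The authors deposited a table of FPKM values (fragments per kilobase of exon per 1000000 mapped fragments) for genes with Ensembl identifiers and symbols, per the file headers. The submitters' processing notes name the genome build hg38 and edgeR, without a version or a role for it. The aligner, the read counter, the annotation release and whether counting used strand are not given in the sources used here. The table has 4 columns of values. The names of 2 of them match the labels of the samples studied here, and the other 2 were not used here. The names of those 2 end in 2 where the names of the columns used end in 1, as for second libraries of the same groups.

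FPKM values depend on exon length and on the library total, so both were recovered from the deposited FPKM values. For a given gene, FPKM times exon length times library total must be a whole number of reads. Library totals of 23377161 for DMSO and 22817719 for JNJ-7706621 met this with exon lengths equal to those of GENCODE release 29 for 17325 genes. For the other genes the exon length nearest to the annotated one was taken, within 0.25 to 4 times the annotated length, for which both values were whole within 0.0001 reads. Reads were recovered for 27805 of the 28014 genes above 0 that the annotation held, and they added up to 99.7% of each library total. These reads served for counting intervals, floors, the read numbers given in the text and shares of the library totals, and no test of counts was run. The recovered exon lengths also served where genes were grouped or corrected by exon length.

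Counting intervals are exact 95% Clopper-Pearson intervals of the FPKM ratio, conditional on the sum of both libraries' reads. A gene at 0 in one library was set against a floor of 3 reads in that library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. They say nothing about the spread between cultures.

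The log2 difference of a gene was log2(FPKM + 1) in the JNJ-7706621 library minus log2(FPKM + 1) in the DMSO library. With the pseudocount of 1 it understates the difference of genes with low values. Genes with a mean FPKM of at least 1 over both libraries entered, and a gene was called higher or lower where the log2 difference was at least 1 or at most -1. In the text, genes called 2-fold higher or lower are those that pass this rule of size. A gene with low values can have an FPKM ratio beyond 2-fold without passing it. Each of 25 gene lists was summarised by its median log2 difference and by the percentile of that median among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart under the 2.5 or over the 97.5 percentile. The percentile describes these libraries and is not a p-value.

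AU-rich motifs were counted in the longest annotated 3' UTR of each protein-coding gene, in transcripts of GENCODE release 29 on GRCh38. The motifs were the AUUUA pentamer and the UAUUUAU heptamer. Random lists for these genes were matched on mean expression and 3' UTR length, in 10 bins each. Coordinates are 1-based positions on GRCh38 from the same annotation.

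Genes are named in the text by a rule set before the data were examined. It takes the 12 genes with the most positive and the 12 with the most negative log2 difference among genes with a mean FPKM of at least 5 that also pass the rule of size with pseudocounts of 0.1 and 0.5. Genes without a symbol, Y-linked genes and XIST were passed over. It also takes up to 5 members of each list with the largest difference in size, and HNRNPD, CDK1, CDK2, AURKA, AURKB, MYC, CCND1, CDKN1A, MITF, MKI67, ACTB and GAPDH always. One of the lists and some genes that the rule takes are not reported here. A symbol with several entries was read from the one with the highest mean FPKM. Genes named outside this rule were chosen after their values were seen, and the text says so.

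The calculations were tested on simulated libraries with the recovered exon lengths and library totals and Poisson reads, over 13093 genes. Of 50 genes changed by a factor of 4, 42 passed the rule of size, against 37 of 50 at a factor of 3, 27 of 50 at a factor of 2.5 and 0 of 50 at a factor of 1.5. Counting noise alone put 28 of 12866 unchanged genes past the rule. A list of 40 genes raised by a factor of 1.3 had a higher median than all 10000 random lists. Of 200 lists of unchanged genes, 9 lay outside the 2.5 to 97.5 percentile range. These 200 were drawn at random, each set against fewer than 10000 random lists, so a low share outside was fixed by the design. It says nothing about lists of genes that vary together. Reads were recovered exactly for 1884 of 1899 simulated genes. The simulated exon lengths were themselves recovered ones, so this rate does not check whether those lengths were right.

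Alternatives covered the pseudocount, the filter on low values, 3 rescalings of the libraries, summing entries that share a symbol, a 4-fold rule, unmatched random lists, lists without members that other lists hold, and other matching and 3' UTR choices for the AU-rich genes. Others were added after the data were seen and are named as such in the closing section. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

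Mitochondrially encoded mRNAs were fixed as a list, but 0 of its 13 members have an entry in the table used here. Nuclear pseudogenes of mitochondrial genes, 407 entries, took 11.2% of the library total recovered for DMSO and 11.3% of that for JNJ-7706621. They held 28.7% and 28.2% of the summed FPKM.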

Results

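The series title concerns interference with the binding of AUF1, an RNA-binding protein encoded by HNRNPD, to mRNA and with mRNA degradation. RNA was sequenced from 2 cultures labelled SK-MEL-2, 1 given DMSO and 1 given 1.75 µM JNJ-7706621 for 48 h. The library totals behind the FPKM values were 23377161 reads for DMSO and 22817719 for JNJ-7706621. Recovered reads of listed genes made up 99.7% of each, so the numbers of reads sequenced or mapped may be larger and are not known here. FPKM values were above 0 for 25185 genes in the DMSO library and 25729 in the JNJ-7706621 library, and at least 1 for 13142 and 13256 genes. With 1 library per group no difference given here has a replicate check, and intervals in parentheses are 95% counting intervals.

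The libraries labelled SK-MEL-2 held few reads of pigment cell genes and many of epithelial genes, in both groups. SOX10, the transcription factor of the melanocyte lineage, had 1 read in the DMSO library and 0 in the JNJ-7706621 library. TYR, the tyrosinase of melanin synthesis, had 0 reads in both, which allows up to 0.0425 and 0.0436 FPKM. PMEL, a melanosome protein, stood at 2.00 and 3.71 FPKM and MITF, the melanocyte master regulator, at 2.65 and 2.27 FPKM. In contrast, the keratin genes KRT18 and KRT8 stood at 1117 and 720.0 FPKM in the DMSO library and at 1123 and 703 FPKM in the JNJ-7706621 library. The adhesion genes EPCAM and CDH1 stood at 55.7 and 49.8 FPKM in the DMSO library and at 59.4 and 67.8 FPKM in the JNJ-7706621 library.

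Of the 30 genes in the melanocyte list, 11 had a mean FPKM of at least 1, among them CDH1, which epithelia also express. Their median log2 difference was 0.17, at percentile 90 of random lists, and 1 of them, RAB38, was more than 2-fold higher in the JNJ-7706621 library. MYO5A at -0.65 and MC1R at -0.53 differed the other way by less than the rule of size, and 44.5% of the exon length of MC1R overlaps exons of other genes. Of 24 markers of other cell types, 4 reached a mean FPKM of 1, all epithelial (EPCAM, KRT8, KRT18 and KRT19), with a median of 0.05 at percentile 52.7. Without the filter on low values that list lay at percentile 98.0, above the range of random lists. SOX10, TYR and the marker genes of the plot that the rule did not take were chosen after their values were seen.

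**Figure D1:**
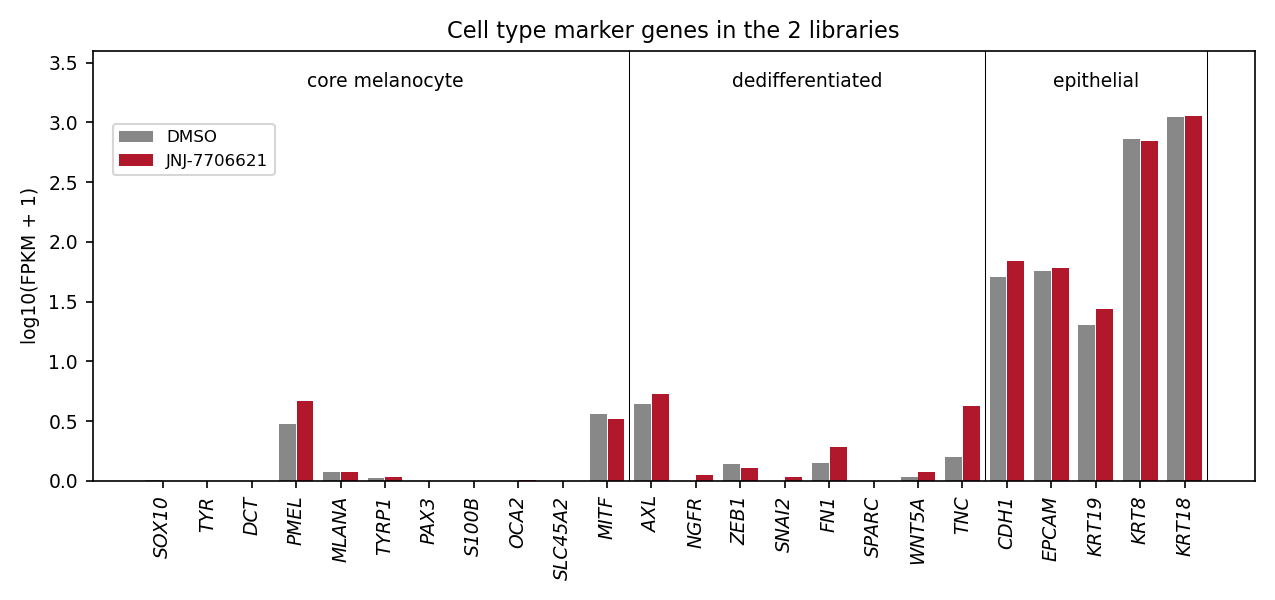
Levels of cell type marker genes in the DMSO library (grey bars) and the JNJ-7706621 library (red bars), as log10(FPKM + 1) with 1 library per bar. Core melanocyte genes reach at most 3.71 FPKM (PMEL), while KRT8 and KRT18 lie at 703 to 1123 FPKM in both libraries.

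The first comparison asked which mRNAs differed between the cultures with and without the kinase inhibitor. Genes of secreted inflammatory factors were the most prominent among those higher in the JNJ-7706621 library. CXCL8, a chemokine that attracts neutrophils, went from 23.2 FPKM in DMSO to 194 FPKM in JNJ-7706621, a ratio of 8.36 (7.87 to 8.88), and CCL2, a chemokine that attracts monocytes, from 3.55 to 30.1 FPKM, a ratio of 8.46 (7.19 to 10). SDC4, a cell surface proteoglycan, was 5.96 times as high (5.70 to 6.23) and the chemokine CXCL1 4.05 times as high (3.93 to 4.18). Fibrinogen genes were lower: FGB stood at 31.2 FPKM in DMSO and 2.93 FPKM in JNJ-7706621, a ratio of 0.0939 (0.0802 to 0.109), FGA at 56.2 and 12.6 FPKM, and FGG at 19.6 and 5.02 FPKM.

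Of 13241 genes with a mean FPKM of at least 1, 316 were at least 2-fold higher in the JNJ-7706621 library and 180 at least 2-fold lower. These counts depend on the settings: they were 608 and 409 with a pseudocount of 0.1, and 714 and 478 after rescaling to a sum of 1000000, which also lowers the weight of the pseudocount and of the filter. Among the higher genes, 283 had a counting interval above a ratio of 1, and among the lower genes 155 had one below 1, a condition added after the data were seen. Protein-coding genes made up 182 of the 316 and 63 of the 180, against 10167 of all 13241. Among genes with a recovered exon length, the tenth with the shortest exons (1311 genes, median 409 bases) held 103 of the higher and 90 of the lower genes. Antisense genes, 1452 of all, numbered 42 and 40, and reads of overlapping genes on opposite strands may not be separable here because the use of strand in counting is not given. The median log2 difference of all these genes was -0.0032, and 96.3% of them lay within 2-fold.

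Others among the 12 most higher were SAA1, PI3, S100A3, TRIML2, CXCL3, HIST1H2BJ and MIR3189. SAA1, an acute phase protein, stood at 8.5 FPKM in DMSO and 45.9 FPKM in JNJ-7706621, and PI3, an elastase inhibitor made by epithelia, at 13.0 and 64.6 FPKM. CXCL3 was 4.19 times as high (3.88 to 4.53), and S100A3 and TRIML2 were 5.48 (4.36 to 6.94) and 6.08 (5.10 to 7.28) times as high. The chemokine genes CXCL8 (positions 73740506 to 73743716), CXCL1 (73869393 to 73871242), CXCL3 (74036589 to 74038807) and CXCL2 (74097035 to 74099293) lie in 1 cluster on chromosome 4. MIR3189, at 18386562 to 18386634 on chromosome 19, lies within the bounds of GDF15 on the same strand and rested on 2 and 18 reads.

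Among the 12 most lower, besides the fibrinogen genes, NOG, an antagonist of bone morphogenetic proteins, had a ratio of 0.136 (0.105 to 0.175) and ID4, an inhibitor of DNA binding by helix-loop-helix factors, a ratio of 0.325 (0.287 to 0.367). VCAN, the matrix proteoglycan versican, stood at 38.6 FPKM in DMSO and 12.6 FPKM in JNJ-7706621. Its antisense gene VCAN-AS1, with 51.7% of its exon length overlapped by exons of other genes, stood at 50.1 and 15.5 FPKM. H1F0, a linker histone of resting and differentiating cells, stood at 103 and 33.1 FPKM. SAMD11, IGFBP1 and the complement factor gene CFD had ratios of 0.230 (0.212 to 0.248), 0.360 (0.331 to 0.391) and 0.363 (0.330 to 0.399). The olfactory receptor gene OR52J3, at 5046526 to 5047461 on chromosome 11, had 316 reads in the DMSO library and 0 in the JNJ-7706621 library, 103-fold lower against a floor of 3 reads and at least 83.1-fold lower by its counting interval. The reads behind this value were not analysed here, so it is uncertain. FGB (154562956 to 154571086), FGA (154583126 to 154590766) and FGG (154604134 to 154612967) are neighbours on chromosome 4.

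**Figure D2:**
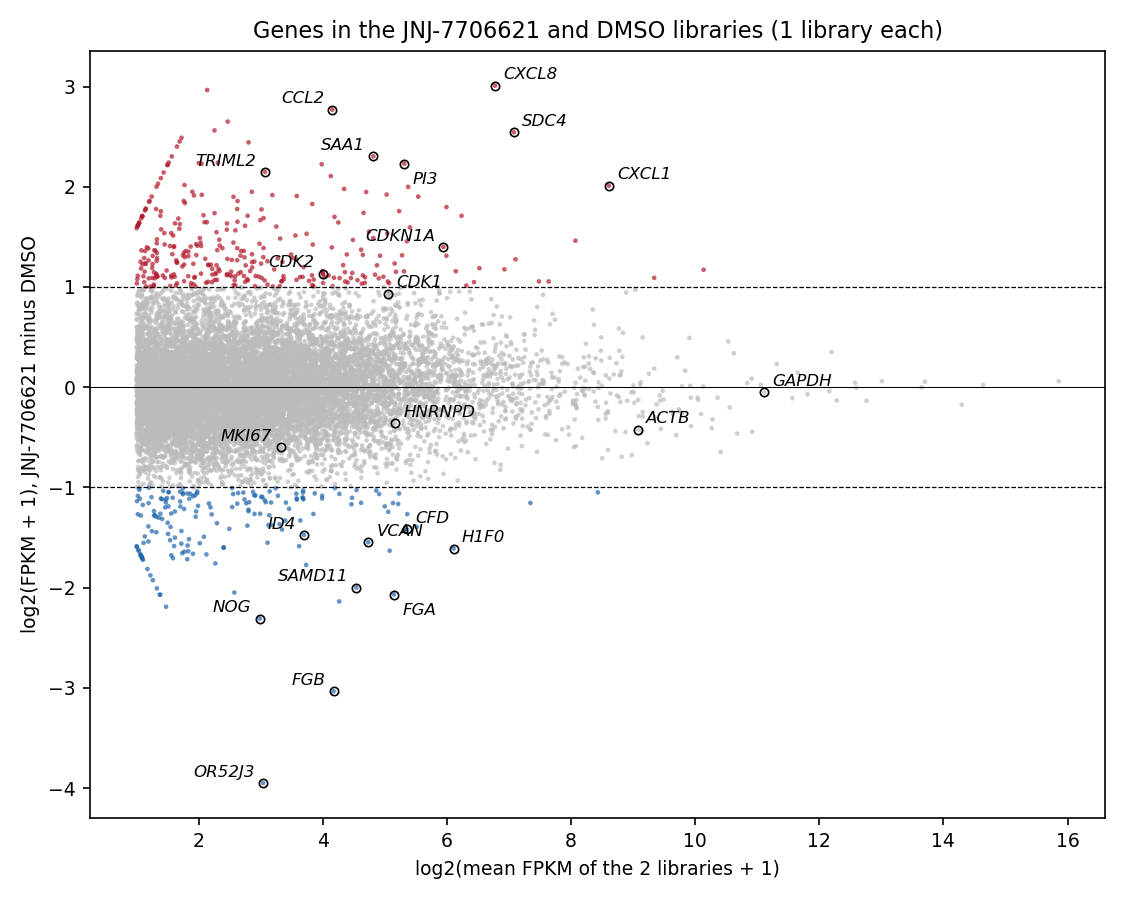
Log2 difference between the JNJ-7706621 and DMSO libraries (vertical axis) against the log2 of mean FPKM + 1 (horizontal axis), 1 point per gene with a mean FPKM of at least 1, Y-linked genes and XIST not drawn. Red and blue points pass the 2-fold rule (dashed lines), CXCL8 lies at 3.01 and FGB at -3.03, and circles mark genes named in the text.

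Cell division genes were compared because JNJ-7706621 inhibits kinases of the cell cycle. DNA replication and G1/S genes stood higher as a group in the JNJ-7706621 library. Of 50 measured members 8 were at least 2-fold higher, 0 were 2-fold lower and 49 lay above 0, with a median log2 difference of 0.64 that 0 of 10000 random lists reached. DSCC1, which helps to load the replication clamp, stood at 5.42 FPKM in DMSO and 15.1 FPKM in JNJ-7706621. GINS2 and GINS4, subunits of the replicative helicase, stood at 4.64 and 12.7 FPKM and at 2.98 and 7.83 FPKM. ORC6 and MCM10, which act in the start of replication, had ratios of 2.53 (2.27 to 2.82) and 2.80 (2.42 to 3.24).

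G2/M and mitosis genes had a median log2 difference of 0.35, also above all 10000 random lists, but went both ways, with 44 of 56 members above 0 and 12 below. CCNB1, the mitotic cyclin B1, was the 1 member past the rule of size, at 55.5 FPKM in DMSO and 116 FPKM in JNJ-7706621. UBE2C, HMMR, MAD2L1 and HJURP had log2 differences of 0.94, 0.91, 0.86 and 0.83. The proliferation marker MKI67 went the other way, at 11.0 FPKM in DMSO and 6.96 FPKM in JNJ-7706621, a ratio of 0.631 (0.596 to 0.667). In a split chosen after the values were seen, the 28 members with shorter exon length had a median of 0.47 (26 above 0) and the 28 with longer exon length one of 0.09 (18 above 0). With the length and GC trend taken off these medians were 0.40 and 0.14.

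The mRNAs of the kinases that the compound inhibits were higher rather than lower in the JNJ-7706621 library, with a median of 0.41 over 8 measured kinases at percentile 99.3. CDK2 stood at 9.06 FPKM in DMSO and 21.1 FPKM in JNJ-7706621 and AURKA at 21.0 and 44.1 FPKM, and these were the 2 members past the rule of size. CDK1 had a ratio of 1.95 (1.85 to 2.06) and AURKB of 1.37 (1.24 to 1.52). CDK6 was the 1 member below 0, with a ratio of 0.716 (0.666 to 0.769).

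Genes of homologous recombination and the replication checkpoint had a median of 0.40 over 22 measured members, which 0 of 10000 random lists reached. XRCC2, which acts in strand exchange, was the 1 member past the rule of size, at 3.3 FPKM in DMSO and 9.21 FPKM in JNJ-7706621, while RMI2, RAD54L and EXO1 had log2 differences of 0.80, 0.76 and 0.57. Replication-dependent histone genes had a median of 0.59 over 21 measured members, above all 10000 random lists, and of 0.16 without the filter on low values, and 4 of the measured members (HIST1H2BJ, HIST1H2BC, HIST1H3B and HIST1H4I) were at least 2-fold higher. HIST1H4I stood at 12.4 and 26.8 FPKM, and HIST1H2BC rested on 12 and 73 reads. Histone mRNAs mostly lack a poly(A) tail and share sequence among their copies, so these values are uncertain.

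CDKN1A, the inhibitor p21 of cyclin-dependent kinases, stood at 32.9 FPKM in DMSO and 88.3 FPKM in JNJ-7706621, a ratio of 2.69 (2.56 to 2.82). BTG2, an antiproliferative factor, had a ratio of 4.33 (3.66 to 5.15). Of 29 apoptosis regulators 2 were at least 2-fold higher, BIK with a log2 difference of 1.25 and BID with 1.04, while TNFRSF10A and BIRC3 had 0.93 and 0.83 and CASP9 -0.94. The list's median was 0.37 at percentile 99.99, and without members that other lists hold it was 0.18 at percentile 96.8, inside the range of random lists.

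**Figure D3:**
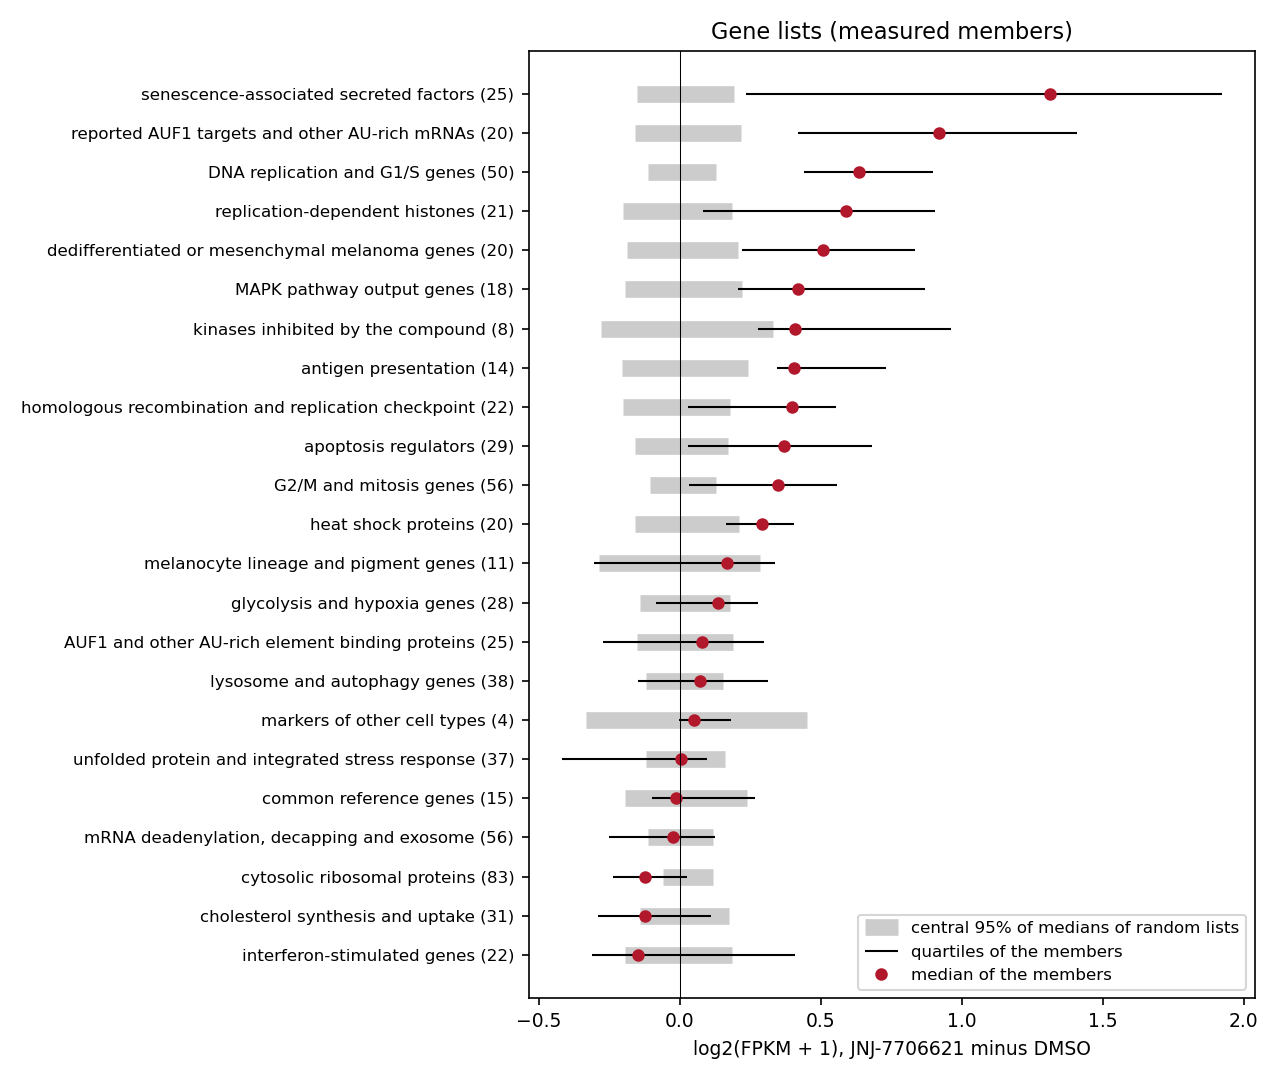
Median log2 difference (red points) and quartiles (black lines) of the measured members of each gene list reported here, with the central 95% of the medians of random lists matched on expression (grey bars). Secreted factors lie highest at 1.31 and interferon-stimulated genes lowest at -0.15, the latter inside the random range.

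The mRNAs that AUF1 is reported to bind were listed along with other AU-rich mRNAs because of the series title. This mixed list is called the AUF1 target list below. Neither AUF1 binding nor mRNA decay was measured, only mRNA levels in 1 library per group. The listed mRNAs were higher as a group in the JNJ-7706621 library, while HNRNPD itself was somewhat lower. Of 20 measured members 9 were at least 2-fold higher and 0 were 2-fold lower, with a median log2 difference of 0.92 that 0 of 10000 random lists reached. Without its 6 measured NF-kB targets, a set chosen after the data were seen, the median was 0.51. Besides CXCL8 and CCL2, members with large differences were CXCL2 at 18.6 FPKM in DMSO and 72.4 FPKM in JNJ-7706621, and the protease gene PLAU at 34.3 and 115 FPKM. Exons of other genes overlap 31.1% of the exon length of PLAU. The cell cycle genes MYC and CCND1 had ratios of 1.22 (1.15 to 1.29) and 1.44 (1.39 to 1.49). HNRNPD, at 82352498 to 82374503 on chromosome 4, stood at 39.2 FPKM in DMSO and 30.3 FPKM in JNJ-7706621, a ratio of 0.774 (0.745 to 0.803).

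The genes encoding AUF1 and other proteins that bind AU-rich elements had a median of 0.08 over 25 members, at percentile 76.2, and 0 of them passed the rule of size. ZFP36L1 and ZC3H12A, which promote mRNA decay, had log2 differences of 0.95 and 0.79, while HNRNPA1, ZFP36L2 and TIA1 had -0.61, -0.57 and -0.57. The deadenylation, decapping and exosome genes had a median of -0.03 over 56 members, at percentile 31.4, with 0 past the rule of size. Their members with the largest differences were UPF2 at -0.81, BTG1 at -0.76, TOB1 at -0.72, DCPS at -0.69 and SMG1 at -0.60.

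Across all protein-coding genes, the medians of genes grouped by AU-rich motifs in the 3' UTR lay close to 0, between -0.09 and 0.04. Genes with 2 or more UAUUUAU heptamers in the 3' UTR, 1472 of them, had a median log2 difference of -0.06, at percentile 10.3 of random lists matched on expression and 3' UTR length. Of these genes 30 were at least 2-fold higher and 12 at least 2-fold lower. The 2063 genes with 1 heptamer had a median of -0.02 (percentile 21.1) and the 6610 genes with 0 heptamers one of 0.02 (percentile 92.0). By the shorter AUUUA pentamer, 2796 genes with 6 or more had a median of -0.09, lower than all 10000 random lists, while 2701 genes with 1 to 2 had 0.04 and 1939 genes with 3 to 5 had 0.04, at percentiles 100 and 99.995. The 2709 genes with 0 pentamers had a median of 0.02 at percentile 12.5. After a trend of the difference with exon length and GC content was taken off, a step added after the data were seen, the genes with 2 or more heptamers had a median of 0.03 at percentile 99.9. The pentamer groups were not corrected for that trend, and their random lists were not matched on GC content. Their percentiles therefore cannot be read as an effect of the motif.

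**Figure D4:**
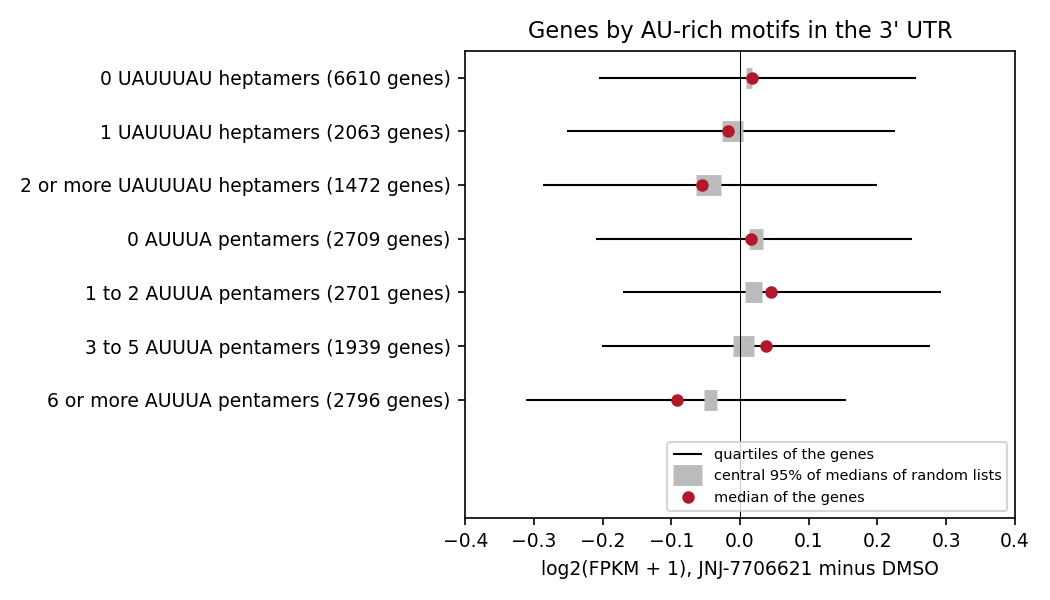
Median log2 difference (red points) and quartiles (black lines) of protein-coding genes grouped by the number of AU-rich motifs in the 3' UTR, with the central 95% of the medians of random lists matched on expression and 3' UTR length (grey bars). The medians run from -0.09 for 6 or more pentamers to 0.04 for 1 to 2 pentamers.

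Secreted factors of arrested, senescent cells had a median of 1.31 over 25 measured members, which 0 of 10000 random lists reached, and of 0.65 without the filter on low values. Of these 15 were at least 2-fold higher and 0 were 2-fold lower. IL1A, an interleukin that drives inflammation, had a ratio of 13.9 (8.85 to 23.2) on 20 and 272 reads. CSF3, the granulocyte growth factor, had a ratio of 9.81 (7.02 to 14.1) on 38 and 364 reads. Genes of the dedifferentiated melanoma state had a median of 0.51 over 20 measured members, above all 10000 random lists, with FOSL1, ANKRD1 and TNC at least 2-fold higher and LOXL2 at 0.93. Output genes of the MAPK pathway had a median of 0.42 over 18 members, reached by 1 of 10000 random lists, and of 0.19 without the filter on low values, and FOSL1 (1.90) and DUSP6 (1.02) were at least 2-fold higher. PHLDA1, SPRY4 and IER3 had log2 differences of 0.91, 0.88 and 0.88 and did not pass the rule of size. The FPKM ratio of SPRY4, at low values, was 3.37 (2.64 to 4.35), above the 2.36 (2.05 to 2.74) of DUSP6. Exons of other genes overlap 40.5% of the exon length of DUSP6.

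Antigen presentation genes had a median of 0.40 over 14 members at percentile 99.9. B2M, the light chain of class I molecules, stood at 51.7 FPKM in DMSO and 105 FPKM in JNJ-7706621, and the immunoproteasome gene PSMB8 at 3.43 and 8.35 FPKM. CTSS and PSME2 had log2 differences of 0.98 and 0.76, and ERAP1 of -0.73. Interferon-stimulated genes did not stand apart, with a median of -0.15 over 22 members at percentile 7.34. OAS3 and ISG15 passed the rule of size, with ratios of 2.71 (2.59 to 2.84) and 2.79 (2.11 to 3.73). GBP2, IFITM3 and IRF7 had log2 differences of 0.79, -0.91 and -0.59 and did not pass it. Their FPKM ratios, at low values, were nevertheless beyond 2-fold, at 2.91 (2.32 to 3.67), 0.471 (0.366 to 0.602) and 0.468 (0.326 to 0.665). Heat shock proteins had a median of 0.29 over 20 members at percentile 99.7, with HSPB8, FKBP4 and AHSA1 at 0.83, 0.72 and 0.64, HSPA8 at 0.50 and HSPD1 at 0.43.

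Genes of the unfolded protein and integrated stress response had a median of 0.01 over 37 members at percentile 38.9, although HERPUD1, CTH, SEL1L, TRIB3 and XBP1 had log2 differences from -0.82 to -0.72. Cytosolic ribosomal protein genes were slightly lower as a group, with a median of -0.12 over 83 members, and 8 of 10000 random lists had as low a median. RPL10 and RPS29 had log2 differences of -0.64 and -0.49, and RPL22L1, RPL39L and RPS10 of 0.86, 0.70 and 0.48. Exons of other genes overlap 55.5% of the exon length of RPL10 and 39.4% of that of RPS10. Cholesterol genes had a median of -0.12 over 31 members at percentile 4.25 (1.5 after rescaling to a sum of 1000000), with FADS1, INSIG1 and SREBF2 at -0.76, -0.56 and -0.43. Lysosome and autophagy genes had a median of 0.07 over 38 members at percentile 81.1, with CTSH and CTSF at 0.75 and 0.64 and CTSD, GABARAP and TPP1 at -0.69, -0.62 and -0.62. The values of CTSD and GABARAP are uncertain, as exons of other genes overlap 52.7% and 55.7% of their exon length. Glycolysis and hypoxia genes had a median of 0.14 over 28 members at percentile 93.7, with ENO2, EGLN3 and PGAM1 at 0.70, 0.66 and 0.63 and BNIP3L and SLC2A3 at -0.66 and -0.62.

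Common reference genes had a median of -0.01 over 15 members at percentile 37.8. GAPDH stood at 2258 FPKM in DMSO and 2180 FPKM in JNJ-7706621 and ACTB at 617 and 460 FPKM, a ratio of 0.746 (0.736 to 0.756). HPRT1 and TFRC had log2 differences of 0.47 and 0.44. B2M was the 1 member past the rule of size.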

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

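Settings named here as added were chosen after the data were seen, and the others before the data were examined. No paired analysis was made because 1 library per group was used and the comparison comes from no test. The other 2 columns of values, named as for second libraries of the same groups, were not used, so agreement with them is not known. The main gene lists reported here (kinases, mitosis, replication and AUF1 targets) kept their sign and stayed above the range of random lists in each alternative run. Without a filter on low values, the AUF1 target list had a median of 0.64 in place of 0.92, since its members near 0 FPKM then entered. The counts of genes depended on the setting. Genes higher and lower numbered 608 and 409 with a pseudocount of 0.1, 145 and 75 with a mean FPKM of at least 5, 714 and 478 after rescaling to a sum of 1000000, and 28 and 10 with the 4-fold rule. With a pseudocount of 0.5, 274 genes were lower. Among protein-coding genes alone, an added setting, 182 were higher and 63 lower, so 74.3% of those called were higher against 63.7% of all called genes. The other rescalings left both counts within 1.5 times.

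Genes with 2 or more heptamers had medians of -0.024 with a mean FPKM of at least 5, -0.015 without a filter, -0.084 after rescaling to a sum of 1000000, -0.080 by trimmed mean of M values and -0.080 without mitochondrial pseudogenes (added). Their percentile was 0.01 without a filter, 1.58 after rescaling to a sum of 1000000 and 0 with matching on expression alone. With the length and GC trend taken off (added), the median was 0.032 at percentile 99.9, and the cause of these shifts was not tested beyond that trend. Of 1269 log2 differences of named genes under alternatives, 45 moved beyond their counting interval, 26 of them with a pseudocount of 0.1. Changes of the filter leave a gene's difference as it is, so those settings could not move any. Of the genes past the rule of size 0 changed sign, which says little. Pseudocounts cannot change a sign, and the rescalings changed the ratio between the libraries by at most 0.0287 on the log2 scale. Depth limits the genes with few reads: counting noise alone put 28 of 12866 simulated unchanged genes past the rule, 3 of 6897 with a mean FPKM of at least 5.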

Other observations

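The tests of the cell identity were chosen after its values had been seen, and those of the replication genes and the AU-rich mRNAs were written before their results were seen. The genes named in this paragraph and the next were picked for the text after their values were seen, whereas the NF-kB target list was set before the values of its 25 unseen measured members were looked at. Collagen genes stood out in a scan of 161 families of protein-coding genes that share the start of their symbol, where 3 families lay above and 11 below the central 95% of random lists, against 8.05 expected by chance. The 12 measured collagens had a median log2 difference of 0.89, which 0 of 10000 random lists reached, and 4 were at least 2-fold higher in the JNJ-7706621 library. COL7A1, the anchoring fibril collagen of skin and mucosa, stood at 8.76 FPKM in DMSO and 24.6 FPKM in JNJ-7706621, and COL4A1 and COL4A2, the common basement membrane chains, at 2.91 and 7.57 FPKM and at 5.10 and 11.2 FPKM. COL4A3 and COL4A4, chains of specialised basement membranes, went the other way, at 5.60 and 2.71 FPKM and at 9.76 and 4.64 FPKM.

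Genes of the NF-kB pathway differed to unlike degrees, and only NFKB2 among its measured subunits was at least 2-fold higher in the JNJ-7706621 library. NFKB2 stood at 10.9 FPKM in DMSO and 31.9 FPKM in JNJ-7706621, RELB at 3.02 and 5.78 FPKM and NFKBIA at 29.5 and 57.4 FPKM, while RELA stood at 12.2 and 12.5 FPKM. TNFAIP3, an inhibitor of the pathway, stood at 1.78 and 8.53 FPKM. In the AUF1 target list, the 14 measured members with a UAUUUAU heptamer in the 3' UTR had a median log2 difference of 0.89 and the 6 without one a median of 0.99. Among 47 measured targets of NF-kB the medians were 1.74 for 24 with a heptamer and 0.79 for 23 without, but 18 of those 24 and 4 of those 23 had been seen before the list was set. Among unseen targets, in a split chosen after the result was seen, 6 with a heptamer had a median of 1.02 and 19 without one of 0.75.

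CXCL8, CCL2 and other mRNAs of the AUF1 target list were higher in the JNJ-7706621 library, though CCL2 has 0 heptamers, and 2 explanations were tested. Against the first, that mRNAs with AU-rich 3' UTRs were higher in general, 1448 genes with 2 or more heptamers outside the AU-rich, secreted factor and NF-kB lists had a median of -0.06, at percentile 4.36, but with the length and GC trend taken off, a test chosen after that result was seen, the median was 0.02 at percentile 99.8. A general difference of that small size is not ruled out, and it is far below the 0.92 of the AUF1 target list. The second was that NF-kB target genes were higher with or without AU-rich elements. The 19 targets without a heptamer, whose values had not been looked at, had a median of 0.75, at percentile 100 of random lists. Lack of the heptamer is not lack of all AU-rich elements, and AUUUA pentamers of these 19 genes were not examined. The result therefore covers the heptamer alone and does not separate the 2 explanations. NF-kB activity is thus a candidate explanation, and slower decay of a part of the AU-rich mRNAs stays open, since the AUF1 target list without NF-kB targets had a median of 0.51 over 14 genes and mRNA decay was not measured.

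The DNA replication genes were higher in the JNJ-7706621 library although the compound inhibits cell cycle kinases, and 2 technical explanations were tested. A trend of the difference with GC content was present, from a median of -0.14 among genes of the lowest GC content to 0.09 among genes near 49.9% GC. With the length and GC trend taken off, the replication genes had a median of 0.56 against 0.64 before, still above all 10000 random lists. Scaling by a few abundant genes was tested by 3 rescalings, under which the lowest median was 0.61. An arrest that leaves more cells in S phase or G2 may account for the pattern as a hypothesis, untested here, as cell cycle phases were not measured and each group has 1 library.

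The libraries labelled SK-MEL-2 held few reads of core melanocyte genes, and 3 explanations were set against each other. Reads of the melanocyte genes lost in counting, where exons of another gene overlap, are argued against by a median overlap of 0% of exon length over the 19 list members with a mean FPKM under 1. A dedifferentiated melanoma state stays open: 20 of the 29 genes of that list with an entry, AXL, ZEB1 and FN1 among them, lay under 5 FPKM in DMSO, but 7, EGFR, VIM and TGFBI among them, lay over 10 FPKM. The 8 genes of that list drawn in the marker plot all lay under 5 FPKM in DMSO, with 0 reads of NGFR, SNAI2 and SPARC. The 5 epithelial genes drawn there all lay over 10 FPKM. These levels go against that state, but genes picked after their values were seen cannot test it. A culture of another, epithelial line under this name stays open too, as the genes that raised this possibility cannot test it and genotypes were not analysed here. Abundant genes were AKR1B10, KRT81, ALDH1A1 and MUC5B, chosen after their values were seen and the last a mucin of airway epithelium, at 2113, 1662, 1196 and 224 FPKM in DMSO.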
